A study of Rattus norvegicus with 112 samples.

How the data were processed

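The series holds 112 Affymetrix arrays of RNA from primary cultures of rat cortical neurons. The cultures were exposed to NMDA, an agonist of the NMDA class of glutamate receptors, to nicotine, or to a compound named 4R. Per the labels, 4R is a non-competitive antagonist of nicotinic receptors. Each array read 1322 probe sets, of which 59 were hybridization or labelling controls and were left out, so that 1263 remained. The probe annotation paired 1137 of these with 1 gene, 8 with several genes and 118 with none. The named probe sets covered 720 genes. No symbol changed when it was looked up again through its Entrez ID, and 8 Entrez IDs were not found in the RefSeq table. Genes were named only from probe sets with 1 gene.

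The deposited values were read as linear intensity, and the software that made them was not given in the sources used here. Within each processing run the mean of each array's values, with 2% trimmed at each end, lay between 2503 and 2513, so the arrays had been scaled to a common mean by the authors and were scaled no further. Values were turned into log2 after adding an offset, the 10th percentile of the positive values of the run. In each run, probe sets whose mean lay below the 30th percentile were left out, which left 884 for the test. The number of arrays limits the precision of every value.

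Group means were fitted with limma 3.58.1 in R 4.3.3, over all groups of a run together, with an intensity trend in the variance. P-values were adjusted by the Benjamini-Hochberg method over the probe sets of a contrast, 2-sided, with a threshold of 0.05. Each SE is limma's. The samples, the contrasts, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. The rule named, per contrast, the 10 probe sets with the largest rise and the 10 with the largest fall among those past the threshold whose treated arrays all lay on the same side of the control mean. For nicotine plus NMDA against NMDA the NMDA mean took the place of the control mean, and interactions and differences between effects were ranked by size alone. Members of the gene lists past the threshold were added. Where fewer than 5 probe sets passed, the 5 with the smallest p were given as values that did not pass. Subunits of nicotinic receptors were given in the nicotine and 4R contrasts and those of NMDA receptors in the NMDA contrasts, passed or not. Probe sets with no gene or with several were counted and not named, except by their probe set ID where a result rests on them.

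The 21 gene lists held immediate early and activity-regulated genes, ionotropic glutamate receptors, metabotropic glutamate receptors, GABA and glycine receptors, nicotinic receptors, muscarinic receptors with acetylcholine synthesis, sodium and calcium channels, potassium channels, synaptic vesicle genes, postsynaptic scaffold and calcium signalling genes, neurotrophic factors with their receptors, cell death genes, stress genes of the heat shock, oxidative and endoplasmic reticulum responses, inflammation genes, neuropeptides and granins, and proliferation genes. They also held markers of neurons, astrocytes, oligodendrocytes, microglia, and endothelial or meningeal cells. Each gene stood for its probe set with the highest mean. Lists with at least 4 tested genes were tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast.

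The arrays came from 10 runs, and each run with replicated groups was fitted separately, except where nicotine was set against 4R. In the continuous experiment, cultures stayed in 1 mM NMDA until harvest after 10, 30, 60, 180 or 360 min. In the pulse experiment, NMDA was washed off after 10, 30 or 60 min and the cultures were harvested 24 h later. A second pulse set with 1 array per group had no replicates, and 4 repeat arrays of pulse samples were used only as alternatives. The crossed experiment combined 10 uM nicotine for 18 h with 1 mM NMDA for 60 min. The washed-out experiment combined 10 uM nicotine for 18 h with a 30 min NMDA pulse, both washed off 24 h before harvest. It was hybridized in a pair of runs. Its repeat run, which the labels describe as a rerun of the same samples after an oven failure, gave the main values, and its first run was an alternative. The labels do not state which run's arrays the failure affected. The remaining runs held nicotine for 15 min with harvest 45 min after the medium change, 2 uM 4R for 18 h, and 2 uM 4R for 18 h followed by 24 h without it. Replicate 1 of the 30 min pulse group carries 60 min in 1 field of its labels and 30 min in the others. It was kept with the 30 min group and left out as an alternative.

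Nicotine was set against 4R as the difference between their effects against their own controls, since they were run separately. Both runs entered the same fit of group means, so the SE, intervals and p-values there pool the spread of both runs. Agreement between a pair of effects was the Pearson correlation across probe sets, which are not independent replicates. A contrast of 360 against 30 min of continuous NMDA and a contrast of the 60 against the 10 min pulse were added after the values were seen.

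Replicate numbers paired the samples in 4 of the runs. In the pulse experiment and in the crossed experiment, the labels give the same culture day to the same number, and in the 4R 18 h experiment they do so too. The mean correlation of the deviations of arrays with the same number from their group means was 0.285 for the pulses, 0.248 for the crossed experiment and 0.491 for 4R. Across numbers it was -0.0831, -0.123 and -0.245. In the continuous experiment the pairing came from the values, since all 45 correlations between arrays of the same number were over 0.1, the lowest being 0.109 and the mean 0.373, against -0.181 across numbers. Deviations cancel within a group, so the means across numbers follow largely from those within numbers and are no separate evidence. The block by replicate number was fitted as an alternative throughout. In the pulse experiment replicates 3 and 4 carry the same culture day and may not be separate cultures, though the block treated them as separate. Its p-values may therefore measure in part only the spread between samples. The labels of the continuous, washed-out and nicotine 15 min experiments do not state that the replicates were separate cultures, so p-values there measure only the spread between samples. In the 4R run with washing, treated replicates 4 and 5 carry the same day, so its p-values may have this limit too.

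Arrays were said to stand apart where their log2 values correlated below 0.9 with the median of the other arrays of the run, a rule chosen after the values were seen. There were 5 among the tested groups. In the repeat run of the washed-out experiment they were control replicate 3 (r = 0.206) and control replicate 4 (r = 0.605). In the pulse experiment they were replicate 3 of the 10 min pulse (r = 0.784) and replicate 4 of the 60 min pulse (r = 0.848). In the continuous experiment it was replicate 3 of 360 min (r = 0.872). The 3' to 5' signal ratio of GAPDH was 2.61, 12.3 and 2.25 on the last 3 of these arrays. These arrays stayed in the main values, and every count was computed again without them. At 360 min this leaves only replicates 2 and 4.

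The alternatives tried were quantile normalization within the run, centring on the array median, an offset at the 25th percentile, no filter and a filter at the 50th percentile, the replicate block, leaving out each array in turn, and a fit of only the groups compared. For the washed-out experiment the first run and the mean of both runs were tried. Scaling moved the median log2 change of all tested probe sets by over 0.1 in 6 contrasts. After NMDA in the washed-out experiment it was 0.03, 0.24 under quantile normalization, 0.14 under median centring and 0.16 in the first run. After nicotine there it was -0.09, 0.23, 0.18 and 0.11, for their interaction 0.05, -0.25, -0.19 and -0.09, and for nicotine minus 4R after washing -0.08, 0.29 and 0.26, with no value for the first run. Median centring moved it from 0.01 to -0.10 at 360 min and from -0.11 to 0.01 after the 60 min pulse. Counts past the threshold were compared with those of other splits of the same samples, up to 100 per contrast.

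The procedure was tested on simulated data with the spread of each run, 884 probe sets and 200 of them changed. At a log2 change of 1 it recovered 54% for 60 min of continuous NMDA, 26% for the 10 min pulse, 68% for NMDA in the crossed experiment, 26% for NMDA in the washed-out experiment, 86% for nicotine for 15 min, 60% for 4R for 18 h and 54% for 4R washed out. At a log2 change of 2 it recovered 80%, 80%, 86%, 70%, 90%, 90% and 90%. At most 6.85% of calls were false. The Benjamini-Hochberg threshold is easier to pass with 200 changed probe sets than where few change. Recovery with few changed probe sets was not simulated and may be lower. These shares therefore do not give the power of contrasts with few or no calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.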

Results

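Gene expression was measured on arrays in primary rat cortical neurons in 8 experiments. The continuous NMDA experiment had 18 arrays, 3 in each of 6 groups from control to 360 min. The pulse experiment had 16 arrays, 4 each for control and for pulses of 10, 30 and 60 min with harvest 24 h later, and a second pulse set had 1 array for each of these. The crossed experiment had 12 arrays, 3 each for control, nicotine, NMDA and both. The washed-out experiment had 20 arrays in each of its runs, 5 each for control, nicotine, NMDA and both. Nicotine for 15 min, 4R for 18 h and 4R for 18 h followed by washing had 3 treated and 3 control arrays each. Another 4 arrays repeated pulse samples, and the values of 1 of them matched those of replicate 3 of the 10 min pulse to within 0.05 at all 1322 probe sets; which run that array came from is not given in the sources used here. Fold changes are given as log2 with the SE of the fit.

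The continuous experiment followed how expression moved while NMDA stayed on the neurons. After 60 min the transcription factor genes Fos, Egr1 and Nr4a1 rose in 3 of 3 arrays. Fos (X06769cds_at) rose by 3.23 (SE 0.71), from a signal of 563 ± 285 to 6129 ± 2641 (SD, n = 3), and Nr4a1 (U17254_g_at) rose by 3.12 (SE 0.67). Egr1 rose at 3 of its 4 probe sets, by 2.75 (SE 0.50), 2.29 (SE 0.45) and 2.19 (SE 0.46), and the unnamed probe set U75397UTR#1_s_at rose by 2.36 (SE 0.40). After 180 min Fos rose at 3 probe sets, by 3.60 (SE 0.71), 3.33 (SE 0.71) and 2.36 (SE 0.46), and Nr4a1 by 3.26 (SE 0.67), again in 3 of 3 arrays. No probe set fell past the threshold at either time.

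By limma, 6 of 884 probe sets passed at 60 min, with adjusted p from 0.0140 for U75397UTR#1_s_at to 0.0389 for Fos, and 4 at 180 min, with adjusted p from 0.0403 to 0.0432. At 10, 30 and 360 min 0 passed, with 63, 16 and 72 at an unadjusted p under 0.05. With the replicate block the counts were 4 at 30 min, 8 at 180 min and 10 at 360 min, 9 of which rose, and without the 360 min array that stands apart they were 1, 11, 12 and 16 at 30, 60, 180 and 360 min. With both the block and that array left out they were 7, 11, 16 and 18. At 60 min the count was 0 under median centring and 3 under quantile normalization, and at 180 min it was 0 under either and 0 when only the 2 groups were fitted. That fit gave 8 at 30 min and 10 at 60 min. Without control replicate 2, control replicate 4, or replicate 2 or 4 of the 60 min group, 0 passed at 60 min. At 180 min 0 passed without any 1 of control replicates 2, 3 and 4 or replicates 2 and 4 of the treated group, and 11 without its replicate 3. At 360 min 1 passed without control replicate 3 and 16 without replicate 3 of that group.

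At 30 and 360 min the smallest p-values belonged to genes of the same kind, none past the threshold with all arrays and no block. At 30 min Egr1 was at 2.38 (SE 0.50, adjusted p = 0.0681) and 2.09 (SE 0.45, adjusted p = 0.0681), and the latter probe set, AF023087_s_at, had an adjusted p of 0.0411 without the array that stands apart. Fos was at 2.64 (SE 0.71, adjusted p = 0.347). With the replicate block both Egr1 probe sets passed (adjusted p = 0.0127), as did Fos (adjusted p = 0.0237). At 360 min Bdnf, which encodes a neurotrophin, was at 2.77 (SE 0.53, adjusted p = 0.0577), Fos at 2.23 (SE 0.46, adjusted p = 0.0577) and Nr4a1 at 2.83 (adjusted p = 0.0914), and with the replicate block these passed (adjusted p = 0.00937, 0.00565 and 0.00358). Leaving out the array that stands apart leaves only replicates 2 and 4 at 360 min. On these Bdnf was at 3.34, 3.25 and 2.75 at 3 probe sets, all past the threshold. So were Fosl2 at 3.23, Junb at 2.96, Crem at 2.79, Igf1 at 2.36 and Vgf at 1.82. At 10 min the smallest p-values included those of rc_AA963674_at at -1.36 (SE 0.33, adjusted p = 0.333), of Eef2, a translation elongation factor, at -1.01 (rc_AA892801_g_at, adjusted p = 0.351), and of Syt11, a synaptotagmin, at -1.43. The annotation gives rc_AA963674_at to Eef2 and rc_AA963674_g_at, made from the same sequence, to Map2k2, so the gene of either is unsure. The 3' to 5' signal ratio of GAPDH, a measure of RNA integrity, was 2.41, 2.27 and 1.61 on the 10 min arrays and 1.29, 1.75 and 1.45 on the controls of the same numbers, so RNA quality and NMDA were not separated there.

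**Figure D1:**
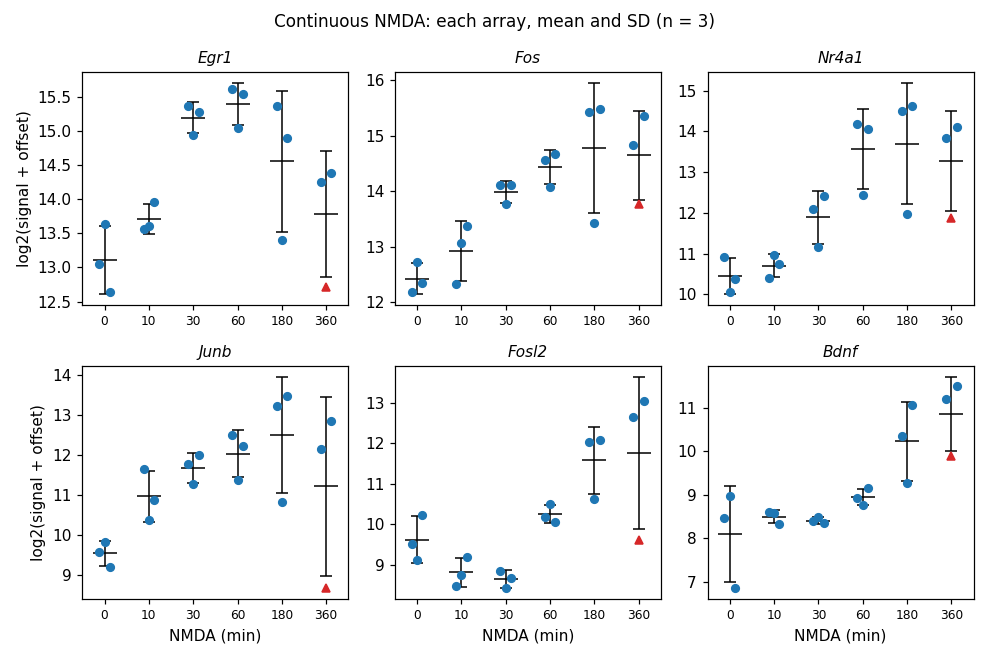
Log2 signal of Egr1, Fos, Nr4a1, Junb, Fosl2 and Bdnf on each array by minutes in 1 mM NMDA; bars show the mean and SD, n = 3, and the red triangle is the 360 min array that stands apart. Egr1 was above the control mean in 3 of 3 arrays at 30 and 60 min, and Fosl2 and Bdnf had their highest means at 360 min.

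Immediate early and activity-regulated genes, which neurons induce after strong input, rose as a list of 16 tested genes in the camera test from 30 min on. The median change was 0.08 at 30 min (adjusted p = 0.0148), 0.47 at 60 min (adjusted p = 2.39e-12), 1.14 at 180 min (adjusted p = 6.49e-24) and 1.07 at 360 min (adjusted p = 5.41e-13). With an estimated correlation the call held at 180 min (adjusted p = 0.00385) and was lost at 30, 60 and 360 min, with adjusted p = 0.928, adjusted p = 0.0613 and adjusted p = 0.0509 with an estimated correlation. Over all genes tested 0, 2, 2 and 0 members rose at these 4 times, and adjusted over the list alone 2, 4, 8 and 8 did. The 6 tested NMDA receptor subunits passed at no time, with Grin2a lowest at 60 min (-0.92) and 180 min (-1.22). Neuropeptides and granins had an adjusted p of 0.223 at 360 min and 0.0120 without the array that stands apart.

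The pulse experiment asked what remained a day after NMDA had been washed off. At 24 h after each of the 3 pulses, 6 genes were higher past the threshold in 4 of 4 arrays: Bdnf, Fos, Nr4a1, Nr4a3, Crem, a transcription factor of the cAMP response, and Penk, the precursor of enkephalin peptides. Bdnf (D10938exon_s_at) was higher by 3.12, 2.68 and 2.90 (SE 0.40) after 10, 30 and 60 min, with signals of 5832 ± 2211, 4111 ± 1182 and 4881 ± 1519 against 621 ± 338 in control (SD, n = 4). Fos (X03347cds_g_at) was higher by 3.10, 2.65 and 2.72 (SE 0.45) and Nr4a1 by 2.76, 2.22 and 2.44 (SE 0.39). Crem was higher by 2.42, 2.08 and 2.12 (SE 0.45), Penk by 1.86, 1.74 and 1.83 (SE 0.39) and Nr4a3 by 1.41, 1.45 and 1.57 (SE 0.34).

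Igf1, a growth factor gene, passed after the 10 and 30 min pulses, at 1.89 and 1.99 (SE 0.45). Adrb1, an adrenergic receptor gene, and Jun passed after the 10 and 60 min pulses, Adrb1 at 1.79 and 1.90 (SE 0.38) and Jun at 1.33 and 1.47 (SE 0.34). After the 10 min pulse Nptx2, which encodes a secreted synaptic pentraxin, was at 2.29 (SE 0.56), Junb at 1.75 (SE 0.43), the neurofilament gene Nefl at 1.58 (SE 0.38), the tachykinin precursor Tac1 at 1.44 (SE 0.36) and the unnamed AF030088UTR#1_at at 1.96 (SE 0.51). Without the arrays of the 10 and 60 min groups that stand apart, Nptx2, Junb and Tac1 were at 2.18, 1.68 and 1.20 and no longer passed (adjusted p = 0.0693, 0.0558 and 0.0690), but they passed with the replicate block and these arrays left out (adjusted p = 0.00199, 0.00266 and 0.0153). Without these arrays Faim2 at -0.98, Scarb1 at -1.29 and the unnamed X07287cds_s_at at -1.48 passed. The NMDA receptor subunits, 6 of 6 tested, passed after no pulse, with Grin2a at -0.26 and -0.27 after 10 and 30 min.

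By limma 20, 12 and 14 of 884 probe sets passed after the 10, 30 and 60 min pulses, and all of them rose. The smallest adjusted p-values were those of Bdnf, 0.000316, 0.00264 and 0.000879. The counts with the replicate block were 20 after 30 min and 23 after 60 min, and with the block and without the arrays that stand apart 51 (32 rose), 43 (31 rose) and 38 (31 rose). When only the groups compared were fitted, 9 passed after 10 min. After 10 min, 12, 11, 12 and 10 passed without control replicate 2, control replicate 4, treated replicate 1 and treated replicate 2. After 30 min, 7 passed without control replicate 3, without control replicate 4, without treated replicate 1, whose labels conflict, and without treated replicate 2. After 60 min, 8, 8 and 4 passed without control replicate 2, control replicate 4 and treated replicate 1.

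Across the 3 pulses 11 probe sets of those 6 genes were shared, and the 3 contrasts used the same 4 controls. When the 10 and 60 min pulses were each set against a different pair of control arrays, 2 and 6 probe sets passed and 2 were shared, and with the pairs exchanged 11 and 0 passed and 0 were shared. No probe set differed between the 60 and the 10 min pulse by limma, with 9 at an unadjusted p under 0.05 and 0 with the block, in a contrast added after the values were seen. In the second pulse set, all 20, 12 and 14 probe sets were higher than in its control array, with median differences of 2.34, 2.30 and 1.96, and those arrays were not replicated.

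**Figure D2:**
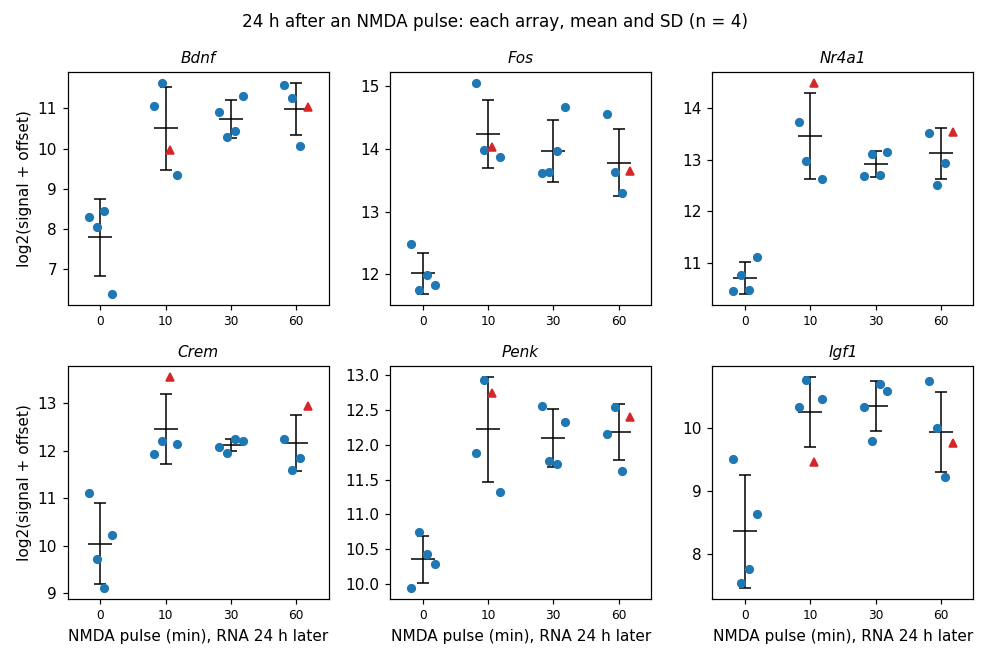
Log2 signal of Bdnf, Fos, Nr4a1, Crem, Penk and Igf1 on each array 24 h after an NMDA pulse of 0, 10, 30 or 60 min; bars show the mean and SD, n = 4, and red triangles are the arrays that stand apart. Bdnf, Fos, Nr4a1, Crem and Penk were higher than the control mean in 4 of 4 arrays after each pulse.

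By list, immediate early and activity-regulated genes rose after all 3 pulses, with median changes of 1.58, 1.48 and 1.43 over 16 tested genes (adjusted p = 2.67e-19, 2.08e-27 and 2.84e-22). Of these 8, 5 and 6 rose over all genes tested, and adjusted over the list alone 11, 10 and 9. Neuropeptides and granins rose too, with medians of 0.84, 0.79 and 0.75 over 9 tested genes (adjusted p = 0.000644, 3.37e-06 and 0.000298). Over all genes tested 1 of them, Penk, rose after each pulse, and adjusted over the list alone 4, 2 and 2 did. In the list Tac1 stood by its brighter probe set M15191_s_at, which was at 0.84 after the 10 min pulse and did not pass (adjusted p = 0.540). The calls of both lists held with an estimated correlation, at adjusted p = 0.00114, 0.000174 and 0.000543 and at adjusted p = 0.0331, 0.00529 and 0.0245. Neuron markers were lower after the 10 min pulse, with a median of -0.56 over 16 tested genes and no member past the threshold (adjusted p = 0.0175). That call was lost with an estimated correlation (adjusted p = 0.210 with an estimated correlation) and without the array that stands apart (adjusted p = 0.530).

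The crossed experiment asked whether 18 h of nicotine alters the early response to NMDA. After 60 min of NMDA, 4 genes rose in 3 of 3 arrays. Fos (X03347cds_g_at) rose by 2.67 (SE 0.20), from 1115 ± 81.3 to 7436 ± 1179 (SD, n = 3), and at its other probe sets by 2.99 (SE 0.48) and 1.94 (SE 0.17). Nr4a1 rose by 2.45 (SE 0.25) and 2.38 (SE 0.19), Junb, a partner of Fos in the AP-1 transcription factor, by 2.19 (SE 0.22), and Egr1 by 1.81 (SE 0.37) and 1.62 (SE 0.27). In cultures that also had nicotine the changes were 2.73 for Fos, 1.90 and 2.36 for Nr4a1, 2.37 for Junb and 1.45 for Egr1 (M18416_at), all past the threshold, while Egr1 at rc_AI176662_s_at was at 1.31 and did not pass (adjusted p = 0.343).

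By limma 8 of 884 probe sets passed for NMDA, with adjusted p from 1.03e-05 for Fos to 0.0436 for Egr1, and 9 passed for NMDA in the presence of nicotine. Nicotine changed the response of none of these genes past the threshold. The difference in the response was 0.07 for Fos (95% interval -0.54 to 0.67), -0.48 for Nr4a1 (U17254_at, -1.07 to 0.11), 0.18 for Junb (-0.50 to 0.85) and -0.16 for Egr1 (-1.01 to 0.68). Over all 884 probe sets 0 passed for this interaction, with 16 at an unadjusted p under 0.05, and the median interval reached 0.939 to either side. Immediate early genes rose as a list with NMDA, with a median of 0.52 (adjusted p = 2.32e-08, and 0.00301 with an estimated correlation), 3 members over all genes tested and 5 adjusted over the list alone. The NMDA receptor subunits, 6 of 6 tested, did not pass, with Grin2a at -0.93 and Grin2c at 0.37. The 3' to 5' signal ratio of GAPDH was 3.36 on control replicate 2 and 2.18 on NMDA replicate 2. On the other arrays of this run it was 1.27 to 1.58. Without control replicate 2, 11 probe sets passed for NMDA and 0 for the interaction by limma.

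**Figure D3:**
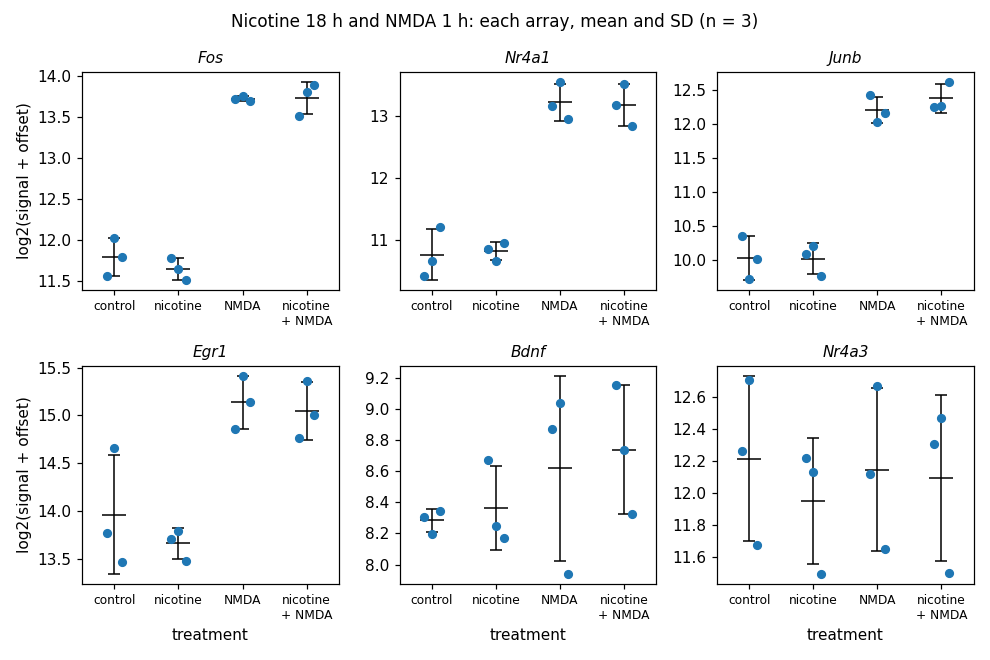
Log2 signal of Fos, Nr4a1, Junb, Egr1, Bdnf and Nr4a3 on each array of control, nicotine, NMDA and nicotine plus NMDA; bars show the mean and SD, n = 3. Fos, Nr4a1, Junb and Egr1 were higher with NMDA in 3 of 3 arrays, with or without nicotine.

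Nicotine by itself for 18 h changed no gene past the threshold in this experiment. The smallest p-values were those of the phosphatase gene Ptprh at -1.25 (SE 0.34), Ins1 at 1.29 (SE 0.38) and the insulin receptor gene Insr at 1.00 (SE 0.33), each with an adjusted p of 0.721. For nicotine plus NMDA against NMDA they were those of the potassium channel gene Kcna5 at 1.66, the serotonin receptor gene Htr1d at -1.89, Fgf2 at 0.90, the sodium channel gene Scn4a at -1.18 and Avp at 1.13. For the interaction they were those of the neurotrophin receptor gene Ntrk3 at 2.38 (0.78 to 3.98), Kcnd2 at 1.06, Pja2 at 0.49, Pnck at 1.62 and the nicotinic subunit gene Chrna3 at 1.16. By limma 0 of 884 probe sets passed for nicotine, with 40 at an unadjusted p under 0.05, and 0 for nicotine plus NMDA against NMDA, with 14. The counts of 0 were the same with the replicate block and under quantile normalization. Of 15 nicotinic subunit genes on the array 11 were tested after nicotine, and they lay between -0.76 for Chrna7 and 0.44 for Chrna4.

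The effects of 60 min of NMDA in the continuous and in the crossed experiment correlated at r = 0.454 across 844 probe sets, which are not independent replicates, with rho = 0.162. Without a filter r was 0.318 and with the filter at the median it was 0.655. In the crossed experiment the NMDA effects without and with nicotine, which used no array in common, correlated at r = 0.340 across 884 probe sets, with rho = 0.104. Without a filter this r was 0.228, and it was 0.184 without control replicate 1 and 0.214 without NMDA replicate 2. It rose to 0.459 without control replicate 2, whose GAPDH ratio was 3.36.

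The washed-out experiment asked what nicotine and a 30 min NMDA pulse left behind after 24 h, alone and together. In the repeat run NMDA raised Nr4a3, a nuclear receptor gene, by 2.29 (SE 0.44), from 2173 ± 1644 to 8052 ± 1501 (SD, n = 5), and Slc2a3, the neuronal glucose transporter gene, by 1.08 (SE 0.22), from 2207 ± 424 to 4693 ± 659, each in 5 of 5 arrays. Without the control replicates 3 and 4 that stand apart, Nr4a3 was at 1.32 and Slc2a3 at 1.15, both past the threshold. There Igf1 at 3.07, the receptor kinase gene Grk3 at 1.94, Nr4a1 at 1.28 and 1.25, Gabrr1 at 1.14 and the nociceptin precursor Pnoc at 0.76 also rose. With all arrays none of these passed, with Igf1 at 2.26 (adjusted p = 0.162), Grk3 at 0.60 (adjusted p = 0.641), Nr4a1 at 0.84 (adjusted p = 0.248) and 1.25 (adjusted p = 0.149), Gabrr1 at 0.65 (adjusted p = 0.366) and Pnoc at 0.34 (adjusted p = 0.453). Scarb1 at -0.94, Map2k2 at -0.84 (rc_AA963674_g_at, whose gene is unsure), the creatine kinase gene Ckb at -0.73, the tubulin gene Tubb5 at -0.72, the presynaptic adhesion gene Nrxn2 at -0.64, Capns1 at -0.52, Eno2 at -0.46 and Camk2b at -0.45 fell. With all arrays 6 of these 8 lay on the other side, Tubb5 at 1.0, Eno2 at 0.75, Map2k2 at 0.28, Capns1 at 0.16, Camk2b at 0.09 and Ckb at 0.02, while Scarb1 was at -0.39 and Nrxn2 at -0.52, none past the threshold.

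By limma 2 of 884 probe sets passed for NMDA (adjusted p = 0.0346 for both genes), 148 had an unadjusted p under 0.05, and 16 passed without the arrays that stand apart, 8 up and 8 down. With all arrays the next smallest p-values were those of Itpka, which encodes an inositol trisphosphate kinase, at -2.00 (adjusted p = 0.0895), Nptx2 at 1.76 (adjusted p = 0.0895) and Abat at 1.26 (adjusted p = 0.0895). The count was 0 under quantile normalization, under median centring and when only the groups compared were fitted, 1 with no filter, 10 with the mean of both runs and 124 in the first run. It was 0 without any 1 of NMDA replicates 1, 2, 3 and 4, 4 without NMDA replicate 5, 17 without control replicate 2 and 18 without control replicate 5. In the first run, 98 probe sets rose and 26 fell, and under quantile normalization 20 rose and 14 fell.

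In the first run NMDA raised Igf1 by 2.04 (SE 0.58), Crem by 1.80 (SE 0.33), the nicotinic subunit gene Chrna7 by 1.70 (SE 0.43), Bdnf by 1.68 (SE 0.31), Nr4a3 by 1.17 (SE 0.17), Fos by 1.13 and Nr4a1 by 1.12. The genes that fell included Itpka at -1.51 (SE 0.34), the kainate receptor gene Grik4 at -1.39, the potassium channel gene Kcnd3 at -1.16, Rnf112 at -1.01, the cell death gene Hrk at -0.74 and -0.49, Scarb1 at -0.67 and Nrxn2 at -0.58. Of these, Igf1, Chrna7, Fos, Rnf112, Hrk at -0.74 and Nr4a1 at U17254_g_at no longer passed in the first run under quantile normalization. In the repeat run without the arrays that stand apart Igf1, Nr4a1, Nr4a3, Scarb1 and Nrxn2 passed and the others did not, with Grik4 at -0.17 (adjusted p = 0.869), Kcnd3 at -0.26 (adjusted p = 0.639), Hrk at -0.54 and -0.63 (adjusted p = 0.30 and 0.0663), Chrna7 at 1.31 (adjusted p = 0.204), Crem at 1.16 (adjusted p = 0.0800), Bdnf at 1.36 (adjusted p = 0.0615), Fos at 1.09 (adjusted p = 0.0941), Rnf112 at -0.95 (adjusted p = 0.0830) and Itpka at -1.56 (adjusted p = 0.0638). The 98 and 26 were compared with the repeat run without the arrays that stand apart, where 86 of 97 tested and 26 of 26 had the same sign. Both runs used the same samples, and the shares over all tested probe sets are not given. The 2 runs' NMDA effects correlated at r = 0.0444 across 856 probe sets, which are not independent replicates, and at 0.629 without those arrays. It was 0.282 without control replicate 3, 0.172 without control replicate 4, 0.190 under quantile normalization, and turned to -0.0519 and -0.0524 without control replicates 2 and 5, and rho was -0.0385. With the pulse experiment's 30 min effect the repeat run correlated at r = 0.156 across 842 probe sets, at 0.360 without the arrays that stand apart, at 0.0876 without control replicate 3 of the pulse experiment, at 0.0910 without a filter, and with rho = 0.0567. Fos, Nr4a1 and Bdnf passed after the 30 min pulse there and not in the repeat run with all arrays, where Nr4a1 passed without the arrays that stand apart, and the difference was not tested.

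Nicotine after washing changed no gene past the threshold in the repeat run. The smallest p-values were those of Kcna4 at -2.22, the dopamine receptor gene Drd4 at -1.70, Grk1 at -1.62 and Bdnf at -1.50, with an adjusted p of 0.202. These values include the control arrays that stand apart, and values without those arrays are not given here. The control signals varied widely, at 2272 ± 1764, 1328 ± 1368, 1329 ± 1253 and 572 ± 303 (SD, n = 5). The falls therefore cannot be read as trends with nicotine. By limma 0 of 884 passed, with 178 at an unadjusted p under 0.05, 0 without the arrays that stand apart, and 6 without control replicate 2. The first run gave 3, Nxph4 at 0.91 (SE 0.16), the heparan sulfate enzyme gene Ndst1 at 0.92 (SE 0.20) and the muscarinic receptor gene Chrm4 at 0.62 (SE 0.13), which in the repeat run without the arrays that stand apart lay at -0.10, 0.53 and 0.29 and did not pass. With all arrays, the 11 tested nicotinic subunit genes lay between -1.40 for Chrna2 and 0.14 for Chrna7.

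For nicotine plus NMDA against NMDA after washing, 0 probe sets passed by limma, with 5 at an unadjusted p under 0.05. The smallest p-values were those of Kcna5 at 1.24 (0.30 to 2.19), the transferrin gene Tf at 1.08, Casp6 at -1.40, the synaptic adhesion gene Nlgn2 at -0.95 and Hcrtr2 at -0.93. Without the arrays that stand apart Tubb5 passed at 0.63 (adjusted p = 0.0411). For the interaction 0 passed, with 34 at an unadjusted p under 0.05, and the smallest p-values were those of Kcna5 at 2.18, Tf at 2.11, the astrocytic calcium-binding gene S100b at 2.90 and Smad9 at 2.37. The interaction values rest in part on the control arrays that stand apart, without which 0 passed too. NMDA with nicotine present gave 0 past the threshold, with 43 at an unadjusted p under 0.05, and 25 without those arrays. Without them the difference in the NMDA response made by nicotine was 0.14 for Nr4a3 (-0.47 to 0.75) and -0.36 for Slc2a3 (-0.91 to 0.19). The NMDA effects without and with nicotine correlated at r = 0.119 across 884 probe sets, at 0.432 without the arrays that stand apart, at 0.298 without control replicate 3 alone, and at 0.0526 and 0.0583 without control replicate 2 and replicate 1 of the group with both.

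**Figure D4:**
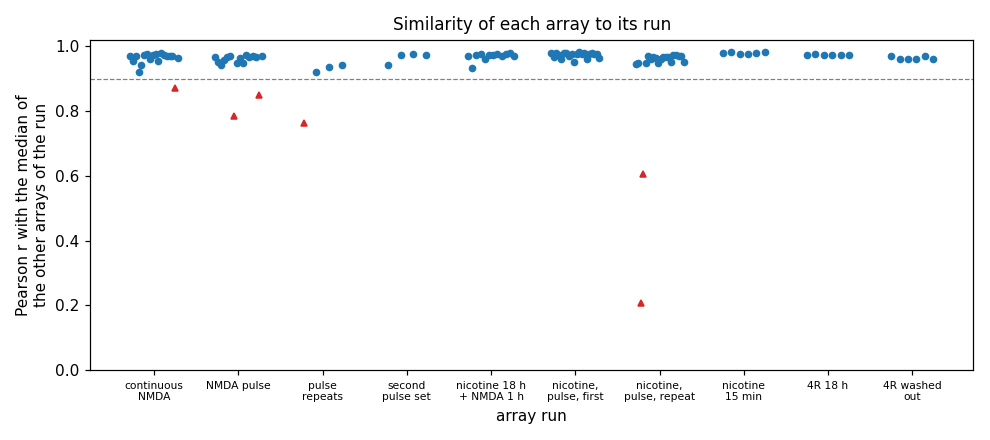
Correlation of each array's log2 values with the median of the other arrays of its run, by run; the dashed line marks 0.9 and red triangles lie below it. Control replicates 3 and 4 of the repeat run of the washed-out experiment lie lowest, at 0.206 and 0.605.

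Of the lists that passed in the washed-out experiment, the immediate early genes alone kept their call without the control arrays that stand apart. Immediate early genes rose with NMDA, with a median of 0.58 over 17 tested genes (adjusted p = 0.000370), 1 member over all genes tested, and 8 up and 1 down adjusted over the list alone. That call held without these arrays (adjusted p = 0.000244) and was lost with an estimated correlation (adjusted p = 0.0962 with an estimated correlation). Stress genes were higher with NMDA (median 1.11, adjusted p = 0.00351) and with nicotine (1.20, adjusted p = 0.00176) and lower in the interaction (-1.16, adjusted p = 0.00216). Muscarinic genes were lower with nicotine (-1.02, adjusted p = 0.00989) and higher in the interaction (0.74, adjusted p = 0.0443), and neuron markers were higher with nicotine (0.81, adjusted p = 0.00989). With an estimated correlation each of these was lost, at adjusted p = 0.641, 0.496, 0.672, 0.496, 0.672 and 0.496 with an estimated correlation, and without the 2 control arrays at adjusted p = 0.90, 0.780, 0.942, 0.729, 0.942 and 0.584. The 6 NMDA receptor subunits did not pass with NMDA, lying between -0.53 for Grin2c and 0.53 for Grin1.

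Nicotine for 15 min, with harvest 45 min after the medium change, changed no gene past the threshold. The smallest p-values were those of Nos2, the inducible nitric oxide synthase gene, at -1.19 (SE 0.29), Rab28 at -0.50, the phosphodiesterase gene Pde4b at -1.0 and the microtubule gene Map1b at -0.74. By limma 0 of 884 probe sets passed, with 29 at an unadjusted p under 0.05 and 1 past the threshold without control replicate 2. The 11 tested nicotinic subunit genes lay between -0.31 for Chrnb1 and 0.40 for Chrna7. The median 95% interval reached 0.462 to either side.

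The 4R experiments asked how the neurons responded to an antagonist of nicotinic receptors. After 18 h the smallest p-values were those of Mog, a myelin gene, at 1.46 (SE 0.29, adjusted p = 0.779), the neurotrophic factor gene Gdnf at 1.63 (SE 0.34, adjusted p = 0.779), Pja2 at -0.87, the G protein gene Gnb1 at -0.77 and the thyroid hormone receptor gene Thra at 0.50. After washing for 24 h they were those of Gcm1 at 1.04, the serotonin receptor gene Htr6 at 1.18, the catenin gene Ctnnd2 at 0.61 and Syt11 at 0.56. By limma 0 of 884 passed after 18 h, with 18 at an unadjusted p under 0.05 and 0 with the replicate block, and 0 after washing, with 14. The 11 tested nicotinic subunit genes lay between -0.50 for Chrna7 and 0.57 for Chrna3 after 18 h, and between -0.43 for Chrne and 0.61 for Chrnb2 after washing.

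Nicotine, an agonist, and 4R, an antagonist, were compared after 18 h, at 10 uM and 2 uM. No gene's effect differed past the threshold. The smallest p-values were those of the kinase gene Map2k1 at -0.88 (95% interval -1.51 to -0.25), Pla2g6 at -0.82, Rab28 at -0.73 and Casp2 at -0.88, where a negative value is lower with nicotine. By limma 0 of 838 probe sets passed, with 22 at an unadjusted p under 0.05, and the median interval reached 0.884 to either side. The nicotinic subunit genes lay between -0.90 for Chrna3 and 0.56 for Chrna4. The effects correlated at r = -0.0216 across 838 probe sets, which are not independent replicates. This r turned to 0.0124 with no filter, to 0.0160 without replicate 3 of the nicotine group and to 0.0407 without replicate 1 of the 4R group, and it was -0.0706 and -0.0686 without replicate 1 of the nicotine group and replicate 3 of the 4R group. The compounds differed in dose and were run separately, so the comparison cannot separate compound, dose and run.

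After washing, the smallest p-values of the difference between nicotine and 4R were those of the protease gene Adam17 at -2.07 (-3.45 to -0.69), Adra1d at -1.70, Gcm1 at -2.19, Kcna4 at -2.18 and Drd4 at -1.84. The values of single genes in this comparison, and the pooled spread behind their intervals, include the control arrays of the nicotine experiment that stand apart. By limma 0 of 841 passed, with 45 at an unadjusted p under 0.05, and the median interval reached 1.42 to either side. The nicotinic subunit genes lay between -1.93 for Chrna2 and 0.52 for Chrne. Stress genes (median 1.25, adjusted p = 0.00155), neuron markers (0.83, adjusted p = 0.0367) and postsynaptic genes (0.40, adjusted p = 0.0194) were higher for nicotine than for 4R, and muscarinic genes lower (-1.06, adjusted p = 0.0194). All 4 calls were lost with an estimated correlation, at adjusted p = 0.558 with an estimated correlation, and without the control arrays that stand apart only the postsynaptic list kept its call (adjusted p = 0.0426). The effects correlated at r = -0.176 across probe sets, at 0.140 without those arrays and at -0.0262 under quantile normalization. This r was -0.0766 without control replicate 3 of the nicotine experiment, -0.0459 without control replicate 5 of the 4R experiment, and -0.0233 and -0.270 without its treated replicates 3 and 4.

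Of the 18 lists with at least 4 tested genes, 12 passed in none of the 21 contrasts. Their smallest adjusted p-values were 0.173 for ionotropic glutamate receptors, for metabotropic glutamate receptors and for potassium channels, 0.223 for nicotinic receptors, 0.283 for GABA and glycine receptors, 0.0935 for sodium and calcium channels, 0.334 for synaptic vesicle genes, 0.197 for neurotrophic factors, 0.196 for cell death genes and for inflammation genes, 0.292 for astrocyte markers and 0.506 for oligodendrocyte markers. Sodium and calcium channel genes passed after the 10 min pulse without the array that stands apart, with a median of -0.47 (adjusted p = 0.0443), but not with all arrays (adjusted p = 0.0935, and 0.841 with an estimated correlation), where 0 members passed. Markers of microglia and of endothelial or meningeal cells had at most 1 tested gene and proliferation genes 0, and were not tested.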

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

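The tests of arrays standing apart, of low-end signal, of washing and of the share of cells were chosen only after the results were seen, as were the contrast of 360 against 30 min, the leaving out of arrays that stand apart and the first run under quantile normalization.

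In 4 of 70 groups 1 array lay far from the others, and chance gives this in about 1 in 20 groups. Bdnf (S71196mRNA_s_at) was at a log2 signal of 7.41 in control replicate 3 of the pulse experiment, with the others between 8.51 and 8.61. Crem was at 13.56 in replicate 3 of the 10 min pulse, an array that stands apart, with the others between 11.94 and 12.20. Fos (X06769cds_g_at) was at 15.06 in replicate 1 of the 10 min pulse, with the others between 13.88 and 14.04. AF030088UTR#1_at was at 6.82 in control replicate 2 of the pulse experiment, with the others between 8.72 and 8.78.

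Between 30 and 360 min of continuous NMDA a set of genes differed by the test of the difference itself, without the 360 min array that stands apart. That leaves only replicates 2 and 4 at 360 min, so these calls rest on few arrays. Fosl2 was higher at 360 min by 4.21 (adjusted p = 3.36e-05), Bdnf by 2.94 (adjusted p = 0.0103), Crem by 2.91 (adjusted p = 0.0308), AF030088UTR#1_at by 2.56 (adjusted p = 0.00689), Vgf, a secreted neuropeptide precursor, by 1.90 (adjusted p = 0.0103) and Nr4a3 by 1.55 (adjusted p = 0.0103). With all arrays 0 of 884 passed by limma, with 61 at an unadjusted p under 0.05, and these differences were 3.13, 2.45, 2.15, 1.54, 1.5 and 1.08. With the replicate block 7 passed, 6 of them higher at 360 min, with Fosl2, Bdnf and Vgf among them and Crem, Nr4a3 and AF030088UTR#1_at not. The 0 of all arrays became 6 without replicate 3 of 360 min, the array that stands apart. Immediate early genes rose as a list from 30 to 360 min, with a median of 0.83 (adjusted p = 5.81e-06), and adjusted over the list alone 7 members rose and 1 fell; the call was lost with an estimated correlation (adjusted p = 0.340 with an estimated correlation).

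Control replicates 3 and 4 of the repeat run of the washed-out experiment stood apart. Too little labelled RNA was argued against by the mean signal of 9 bacterial spike-in probe sets, 1.29 times the median of the other arrays on the lower of these arrays, with up to 1.40 on the 18 others; for it speak the 1.58 of the higher array, the signals of 1 of these probe sets, BioB 5', 4987.05 and 2766.18 against at most 929 elsewhere in the run, and 10th percentiles of signal of 246 and 213 against at most 65.2. An exchange of labels with another array of the series was argued against by the highest correlation of either with any other sample's array, 0.618. The state of the cultures was argued against by the arrays of the same samples in the first run, which correlated at 0.974 or more with their run's median. What stays open is the amount of labelled RNA and a fault in hybridizing or scanning these arrays, which were not told apart.

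In the first run of the washed-out experiment 124 probe sets passed for NMDA, against 2 in the repeat run. The repeat run's count was 16 without the control arrays that stand apart, so part of the gap rests on those arrays. With the block as well it was 53, but the 124 came from a fit without a block. Higher signal at the low end of the first run's NMDA arrays than of its controls is a candidate explanation, with values on both sides. For it, the median change in the lowest of 3 equal bands of signal exceeded that in the highest by 0.41. After quantile normalization 25.8% of the calls remained. Against it, 29 of the 98 probe sets that rose lay in the lowest band, though 17 lay in the highest. Nicotine gave 3 calls there, with 10th percentiles of signal of 56.8 to 80.2 on its arrays. They were 57.6 to 61.5 on the NMDA arrays and 39.8 to 51.5 on the controls. In the repeat run of the same samples, without the arrays that stand apart, 86 of 97 had the same sign. The share of all tested probe sets higher there is not given, so the 86 of 97 cannot be weighed against it. The pulse itself as the source of the probe sets that rose as a set was argued against, since 50.5% of them were higher after the 30 min pulse of the pulse experiment, where 44.0% of all tested probe sets were higher. The probe sets that fell had the values the pulse needs, since 92% of them were lower there, against 56.0% of all, so these may reflect the pulse. Bdnf, Crem, Nr4a1 and Nr4a3 passed after the 30 min pulse and in the first run, where at least 1 probe set of each stayed past the threshold after quantile normalization, and what raised the set as a whole stays open.

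The genes higher 24 h after the NMDA pulses held 20 probe sets, with medians of 2.26, 1.96 and 1.87 after 10, 30 and 60 min. Washing and medium change as their source were not settled. The same probe sets had a median change of 0.0028 in washed nicotine cultures of the first run. In washed 4R cultures it was -0.05, each against its own controls. These values could argue against washing only if those controls were not washed, which was not established here. A changed share of neurons, astrocytes or oligodendrocytes was argued against, since the largest median of a marker list of these cells was 0.359 in size without the arrays that stand apart, while with all arrays the neuron markers had a median of -0.56 after the 10 min pulse. Other splits of the same 8 arrays gave at most 1 call for any pulse. A lasting response of these neurons to NMDA may be the source, as a hypothesis found and tested on the same data. Washing, a loss of neurons and the state of cells that survive the pulse stay open. So does a changed share of microglia, whose markers were not tested.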

How the results depend on the processing

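Leaving out arrays that stand apart, the block combined with it, the first run under quantile normalization and the contrast of 360 against 30 min were chosen only after the data were seen. The 66 named values past the threshold with all arrays kept their sign under every setting run: 954 of their 1216 values stayed past the threshold and 262 did not. Genes named only because they passed without the arrays that stand apart or in the first run are not among them, and some of those had the other sign elsewhere, as the report gives for Tubb5, Eno2, Map2k2, Capns1, Camk2b, Ckb and Nxph4. Of the counts 322 of 399 stayed within 1.5 times, where a 0 that stayed 0 was taken as unchanged. Most contrasts had a count of 0. With 1 array left out, counts moved further in 4 of 6 fits at 60 min and 6 of 6 at 180 min. They did so in 4, 4 and 3 of 8 after the pulses, and for NMDA in 0 of 6 (crossed) and 7 of 10 (washed-out). Of the agreements 100 of 156 stayed within the spread, the SD of the values with 1 array left out. Most of the 156 are those same values, so this share says little about stability. Of the list shifts 183 of 236 kept their call. The cause was not tested except where stated. Probe sets near the background limit what can be seen: signals below the 30th percentile were not tested. With all arrays, changes of 0.5 were recovered in 4% to 38% of simulated cases with 200 changed probe sets. Where few probe sets change, the share may be lower.

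With the replicate block the counts were 4 at 30 min, 8 at 180 min, 10 at 360 min and 7 for 360 against 30 min of continuous NMDA, and 20 and 23 after the 30 and 60 min pulses. It gave 9 at 60 min, 26 after the 10 min pulse and 11 for NMDA in the crossed experiment, and the other counts of paired experiments stayed at 0. All 66 named values stayed past the threshold. Where samples share only a number, the block gave 5 for NMDA in the washed-out experiment; 12 of 20 arrays of the repeat run were closest to their own number, 4 of 6 for nicotine for 15 min and 4 of 6 for 4R washed out, where the block gave 0 and 0. With the second pulse set as a further block the counts were 45, 34 and 33 for 10, 30 and 60 min.

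Without the arrays that stand apart the counts were 1, 11, 12 and 16 at 30, 60, 180 and 360 min, 6 for 360 against 30 min, 16 for NMDA in the washed-out experiment and 1 for nicotine plus NMDA against NMDA there. With the block as well they were 7, 11, 16, 18 and 11, then 51, 43 and 38 after the pulses, 53 (33 up, 20 down) and 2. The agreement of the 30 min pulse in both experiments was 0.360, of the repeat with the first run 0.629, of washed nicotine with 4R 0.140, a reversal, and of NMDA without and with nicotine after washing 0.432. Relative to the other genes, camera's direction reversed for stress genes with NMDA, with and without the block, and for muscarinic genes in the interaction. The own mean change of the stress genes was 0.26, and 0.11 with the block. It stayed positive, so that reversal is only against the other genes, whose means are not given. The own mean of the muscarinic genes was -0.0115.

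Fitting only the groups compared gave 8, 10 and 0 at 30, 60 and 180 min, 9 after the 10 min pulse and 0 for NMDA in the washed-out experiment. Quantile normalization gave 3, 0 and 0 at 60 min, at 180 min and for NMDA in the washed-out experiment, and agreements of 0.190 for repeat with first run and -0.0262 for washed nicotine with 4R. Median centring gave 0 for all 3 of these counts. With no filter the count for NMDA in the washed-out experiment was 1. The agreements with no filter were 0.318 (60 min of NMDA in 2 experiments), 0.0910 (30 min pulse), 0.0124 (nicotine and 4R, a reversal), 0.228 (NMDA without and with nicotine, crossed) and 0.175 (washed-out). With the filter at the median they were 0.655, 0.228 and 0.497 for the first, the second and the crossed experiment, and with the higher offset 0.512 for the first. Spearman's rho was 0.162, 0.0567, 0.104 for the same, and -0.0385 for repeat with first run, a reversal. Leaving out the array with conflicting labels gave 7 after the 30 min pulse, with fewer samples.

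In the washed-out experiment the first run gave 124 for NMDA and 3 for nicotine, 34 under quantile normalization for NMDA, and the mean of both runs 10. In the first run camera's direction relative to the other genes reversed for several lists, whose own mean changes follow. They were 0.21, 0.15 and -0.19 for stress genes with NMDA, with nicotine and in the interaction. For muscarinic genes they were 0.38 and -0.43 with nicotine and in the interaction, and for neuron markers 0.0142 with nicotine. The own means of stress genes and neuron markers kept the sign of the main medians, and those of muscarinic genes did not.

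Leaving out 1 array at a time, which leaves fewer samples, gave 0 to 7 at 60 min, 0 to 11 at 180 min, 0 to 16 at 360 min, 0 to 6 for 360 against 30 min, 10 to 19, 7 to 11 and 4 to 13 after the pulses, 6 to 11 for NMDA in the crossed experiment, 0 to 18 for NMDA and 0 to 6 for nicotine in the washed-out experiment, and 0 to 1 for nicotine for 15 min. Agreements ranged over 0.357 to 0.445 (60 min of NMDA), 0.0876 to 0.232 (30 min pulse), -0.0524 to 0.282 (repeat with first run), -0.0706 to 0.0407 (nicotine and 4R), -0.270 to -0.0233 (the same, washed), 0.184 to 0.459 (NMDA without and with nicotine, crossed) and 0.0526 to 0.298 (washed-out).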

Other observations

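The genes set side by side in the next paragraph, the contrasts of 360 against 30 min and of the 60 against the 10 min pulse, and the tests without the arrays that stand apart were chosen only after their values were seen, and the rule for other splits was written before the splits were made.

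Nefl, which encodes the light neurofilament chain, was past the threshold without the arrays that stand apart after the 10, 30 and 60 min pulses, at 1.19, 1.20 and 1.32 (M25638_s_at). With all arrays it passed after 10 min only (adjusted p = 0.212 after 30 min and 0.111 after 60 min), and its brighter probe set, AF031880_at, was at 0.29 after 10 min (adjusted p = 0.958) against 1.19 without those arrays. Nefl (M25638_s_at) also passed in the first run of the washed-out experiment at 0.78 (SE 0.16), but not in the repeat run without those arrays, where it was at 0.69 (adjusted p = 0.143). Pnoc, the nociceptin precursor, was at 1.07 (SE 0.23) and 0.79 (SE 0.14) at its 2 probe sets in that run, and without the arrays that stand apart at 0.99 (adjusted p = 0.0860) and 0.76 (adjusted p = 0.0165) in the repeat run of the same samples, where with all arrays the latter was at 0.34 (adjusted p = 0.453). In the pulse experiment Pnoc passed after no pulse with all arrays, and with the replicate block after 10 min at S79730_s_at, at 1.40 (adjusted p = 0.0385). With nicotine present in the repeat run, and without those arrays, NMDA raised Nr4a3 by 1.46 (SE 0.19), Bdnf by 1.43 (SE 0.31), Nr4a1 by 1.12 (SE 0.26) and Slc2a3 by 0.79 (SE 0.17), and 25 probe sets passed by limma, where 0 passed with all arrays.

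For the pulses the share of all 35 splits of the 8 arrays was under 0.05, but these splits ignore the pairs. The 8 splits that part all pairs are too few for a share under 0.05, so the splits cannot exclude chance. Only the real split of 35 gave as many calls for the 10, 30 and 60 min pulses, 20, 12 and 14, the highest other split giving 0, 1 and 1, and among the 8 splits that part all pairs 1 gave as many, the highest other giving 0. The same held for the mean of the immediate early genes, 1 of 35, at 1.43, 1.35 and 1.29 against 1.11, 1.01 and 0.993 at most in another split, and for the neuropeptides, 1 of 35, at 0.81, 0.90 and 0.76 against 0.77, 0.73 and 0.74. For the contrast of the 60 with the 10 min pulse all 35 splits gave at least the real 0. A split of replicates 1 and 2 of both groups against 3 and 4 gave 111 calls, the next highest giving 1, which points to a structure of the samples whose cause was not tested. Replicates 3 and 4 carry the same culture day, and that side of the split also holds the 2 arrays that stand apart, replicate 3 of the 10 min pulse (r = 0.784) and replicate 4 of the 60 min pulse (r = 0.848); with the replicate block the count of the real contrast was 0.

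For groups of 3 against 3 the 10 splits are too few for a share under 0.05. The real counts were 0, 0, 6, 4 and 0 at 10, 30, 60, 180 and 360 min of continuous NMDA, with a highest other of 0 each, and 10, 10, 1, 1 and 10 splits gave as many. For 360 against 30 min 10 of 10 did, with 0 against 1. In the crossed experiment NMDA gave 8 against 2, in 1 of 10, nicotine 0 against 0 and nicotine plus NMDA against NMDA 0 against 0, both in 10 of 10. Nicotine for 15 min gave 0 against 1, 4R for 18 h 0 against 0 and 4R washed out 0 against 3, each in 10 of 10. The mean of the immediate early genes was 1.29 at 180 min against 1.04 in another split and 0.76 for NMDA in the crossed experiment against 0.55, each in 1 of 10.

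For larger designs up to 100 splits were drawn. NMDA in the repeat run gave 2 calls, which 2 of 100 splits reached, the highest other being 2. The share was under 0.05, but another split gave as many calls, and the splits ignore the replicate numbers. The count also rests on the setting: 0 passed under quantile normalization, under median centring, when only the groups compared were fitted and without any 1 of NMDA replicates 1 to 4, and 17 and 18 passed without control replicates 2 and 5. Without the arrays that stand apart it gave 16, reached by 1 of 56 splits, the highest other being 3, and in the first run 124, reached by 1 of 100, the highest other being 10. For contrasts with a count of 0 every split reaches it, 100 of 100, so the comparison decides nothing. These were the interaction in the crossed experiment (highest other 1), nicotine (6), nicotine plus NMDA against NMDA (0) and the interaction (1) in the washed-out experiment, and nicotine minus 4R after 18 h (3) and after washing (1). The split with 6 calls for nicotine in the washed-out experiment points to a structure, for which the control arrays that stand apart are a candidate explanation that was not tested on the split; the real count was 0 with the replicate block and 0 without those arrays.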
